A study of Mus musculus with 9 samples.

How the data were processed

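Droplet-based single-cell RNA was measured in CD45+ cells from mouse subcutaneous tumours, with 4 libraries labelled IgG, 4 labelled UM-h101 and 1 labelled only as a repeat group, which was kept out of every comparison because its treatment cannot be told. The deposited matrices hold raw UMI counts, whole numbers per gene and cell barcode, made with Cell Ranger 6.1.2 per the file headers on genome build mm10. The submitters' notes also name Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5, tools for bulk RNA of whose use the files show no sign. Groups, tests, gene lists, marker genes, naming rules and most alternatives were fixed before the data were examined.

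Barcodes with at least 500 UMIs, at least 200 genes and at most 15% mitochondrial UMIs were kept. Doublets were scored per library with the Scrublet method in scanpy 1.11.5, and where its own threshold marked under 0.5% of cells the share expected at 0.8% per 1000 cells was removed. This left 20496, 10332, 10913 and 10313 cells in IgG 1 to 4, 8121, 11159, 11146 and 9551 in UM-h101 1 to 4, and 12250 in the unassigned library. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 40 principal components, and Leiden clusters (leidenalg 0.10.2, igraph 0.11.9) were found on 15 nearest neighbours at a resolution of 1. T and NK clusters were clustered again on their own.

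Clusters were named by the mean standardized level of marker genes per class. A cluster stayed without a name if its best score was under 0.5, if fewer than 3 markers reached 50 CPM, if lymphoid and myeloid scores lay within 0.5 of each other, or if its 10 leading genes held more markers of another class than of its own. Clusters with Ptprc under 100 CPM were set aside as low in Ptprc, and clusters whose monocyte and macrophage scores lay within 0.5 were called intermediates. Class shares are percent of kept cells with a class name, and T-cell classes were also taken as percent of T cells. ILC2, mast cells or basophils and plasmacytoid dendritic cells had under 20 cells in a library and were not tested for expression.

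UMI counts were summed per library and class and tested with edgeR 4.0.16 (TMM normalization, filterByExpr, robust quasi-likelihood test of group) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested in a class and a threshold of 0.05. Depth per summed library ran from 3000962 to 9837610 UMIs in CD8 T cells, 423445 to 1066775 in regulatory T cells and 78581 to 12662936 in neutrophils. Shares, and the difference of an effect between CD8 T cells and other classes on log2 CPM with a prior count of 2, were tested by exact 2-sided permutation over the 70 splits of 8 libraries, so that 0.0286 is the smallest p possible. Other calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.

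Gene lists were tested per class with camera (limma 3.58.1) on voom values at a preset correlation of 0.01, and beside it with an estimated correlation and with fry. The lists cover cytosolic ribosomal proteins, nuclear and mitochondrially encoded oxidative phosphorylation, mitochondrial upkeep, glycolysis, hypoxia, cell cycle, dissociation and stress, type I interferon and interferon-gamma responses, TNF and NF-kB targets, TNF superfamily, chemokines, class I and class II presentation, inflammatory and suppressive myeloid, arginine and polyamine metabolism, T-cell activation, exhaustion, naive and memory, cytotoxic effector and regulatory T-cell genes, and genes of other cell types (neutrophil, macrophage, T, B and plasma, erythroid, and tumour, fibroblast and endothelial). Genes are named if they are among 18 focus genes, if they are among the 10 largest passing rises or falls in CD8 and regulatory T cells or the 5 largest elsewhere, or if they are among the leading members of a passing list. Variable segments of antigen receptors, unnamed gene models and sex-linked genes were left out of those places but not out of counts. Downstream genes, their abundant neighbours and the neutrophil genes read in CD8 T cells are named as exceptions. Genes picked in erythroid cells are counted, but their changes are not given. A fold against a group without UMIs is a lower bound set with 3 UMIs over the group, and a group with 1 to 3 UMIs is given as a ratio with a 95% counting interval. Downstream genes start within 10 kb after the end of an abundant gene on the same strand, by the GENCODE vM21 annotation. An abundant gene reached at least 100 CPM and 4 times the level of the downstream gene. Both levels are means over all kept cells of the IgG and UM-h101 libraries, not levels in a class.

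Detection was tested on simulated data with changes put into the counts. In CD8 T cells edgeR recovered 29.9% of 2-fold and 91.9% of 4-fold changes with 6.25% of calls false, in neutrophils 16.2% and 75.8% with 1.16% false. In cDC1 10.9% of calls were false, the highest of the classes. With only the glycolysis list shifted in simulated CD8 T cells, 3 of 27 other lists also passed camera. Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, leaving out each library in turn, a stricter cell filter (1000 UMIs, 500 genes, 10% mitochondrial), doublets kept, a resolution of 2, counts thinned to the smallest library, other denominators and a centred log ratio for shares, and a prior count of 0.5. Added after the data were seen were a ribosomal-protein share as covariate, leaving out T and NK clusters mostly of 1 library, putting a Ly6c2-led cluster back into CD8 T cells, shares of all kept cells or without erythroid cells, and counts without downstream genes. No per-cell test was used, since cells of 1 library are not replicates.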

Results

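Single-cell RNA was measured in CD45+ cells, the cells that carry the pan-leukocyte protein encoded by Ptprc, from subcutaneous tumours of mice. The labels assign 4 libraries to IgG treatment and 4 to UM-h101, an antagonistic antibody to TNFR2, the TNF receptor encoded by Tnfrsf1b. A further library, labelled only as a repeat group, entered no comparison. All libraries share 1 batch date, and nothing beyond the labels ties each library to a separate animal. The deposited values are raw UMI counts over 32285 genes. The IgG libraries 1 to 4 held 26329, 11518, 12801 and 11330 barcodes with totals of 158932801, 141949659, 141043278 and 152740122 UMIs. The UM-h101 libraries 1 to 4 held 9504, 13633, 12918 and 10964 barcodes with totals of 109499852, 136040627, 138770603 and 134615135 UMIs. Median UMIs per barcode lay between 8097 and 10279 in 7 of these 8 libraries and at 5022 in IgG 1. Changes are log2 fold changes of UM-h101 over IgG ± standard error, and levels are depth-scaled UMI counts (CPM) or percent ± SD, with n = 4 libraries per group throughout. A class name stands for cells that resemble that type by marker genes fixed before the data were examined.

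The first comparison asks which kinds of immune cell made up the tumour infiltrate under each antibody. Neutrophils held 0.492 ± 0.0712% of the cells with a class name in IgG libraries and 11.9 ± 7.79% in UM-h101 libraries, a 24.2-fold ratio of means. Macrophages held 34.6 ± 8.36% and 15.1 ± 5.45%, while cells between monocyte and macrophage by their markers, called intermediates here, held 23.9 ± 8.44% and 43.5 ± 5.01%. Antigen-presenting dendritic cells of the cDC1 type held 0.922 ± 0.387% and 0.402 ± 0.218%, and those of the cDC2 type 5.08 ± 1.26% and 3.14 ± 0.47%. In each of these 5 classes all 4 UM-h101 libraries lay on 1 side of all 4 IgG libraries, which gave the smallest 2-sided p the exact permutation test can reach, 0.0286, and an adjusted p of 0.0971 over 17 classes. No class passed at an adjusted p under 0.05. With that smallest p and 17 classes, no class could have passed on its own, however far apart the groups lay. Monocytes, macrophages and intermediates together held 62.6 ± 10.4% and 64.9 ± 10.6% (exact permutation p = 0.686), and the line between them rests on markers such as Arg1 and the C1q genes that themselves differed between the groups.

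CD8 T cells, the cytotoxic T lymphocytes, held 11.4 ± 5.45% in IgG and 5.9 ± 1.06% in UM-h101 libraries (exact permutation p = 0.0857, adjusted p = 0.182). Regulatory T cells, the suppressive CD4 lineage marked by Foxp3, held 1.64 ± 0.738% and 1.07 ± 0.166% (exact permutation p = 0.257, adjusted p = 0.397). As a share of T cells they held more under UM-h101, 9.74 ± 1.5% in IgG and 12.1 ± 1.5% in UM-h101 libraries (exact permutation p = 0.0857, adjusted p = 0.343), so the sign hangs on the denominator. The log2 ratio of CD8 to regulatory T cells was 2.77 ± 0.37 in IgG and 2.46 ± 0.42 in UM-h101 libraries (exact permutation p = 0.314), a difference that turned from -0.31 to 0.41 without T and NK clusters mostly of 1 library. That setting took out a cluster of 1036 CD8 T cells in IgG and 6 in UM-h101 libraries. Most came from IgG 3, which held 1156 CD8 T cells and kept its regulatory T cells. The turn thus follows from the removal and shows nothing about the ratio itself. Left without a name were 3 clusters of T, NK and innate lymphoid cells. Of these cells, 1 cluster scoring as CD8 T cells but led by genes of another class held 4.88 ± 7.28% in IgG and 0.235 ± 0.0496% in UM-h101 libraries (exact permutation p = 0.0286). Another scoring as CD8 T cells held 3.53 ± 2.11 and 7.35 ± 3.95% (exact permutation p = 0.0571), and 1 scoring as regulatory T cells held 5.17 ± 3.25 and 4.6 ± 3.26% (exact permutation p = 0.8). NK cells held 5.98 ± 2.28% and 5.09 ± 1.66%, conventional CD4 T cells 2.31 ± 1.69% and 0.856 ± 0.246%, and monocytes 4.06 ± 0.614% and 6.24 ± 2.54%. Clusters low in Ptprc, which a CD45+ gate would remove, held 17.4 ± 5.05% of kept cells in IgG and 2.88 ± 0.594% in UM-h101 libraries (exact permutation p = 0.0286, adjusted p = 0.0571).

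**Figure D1:**
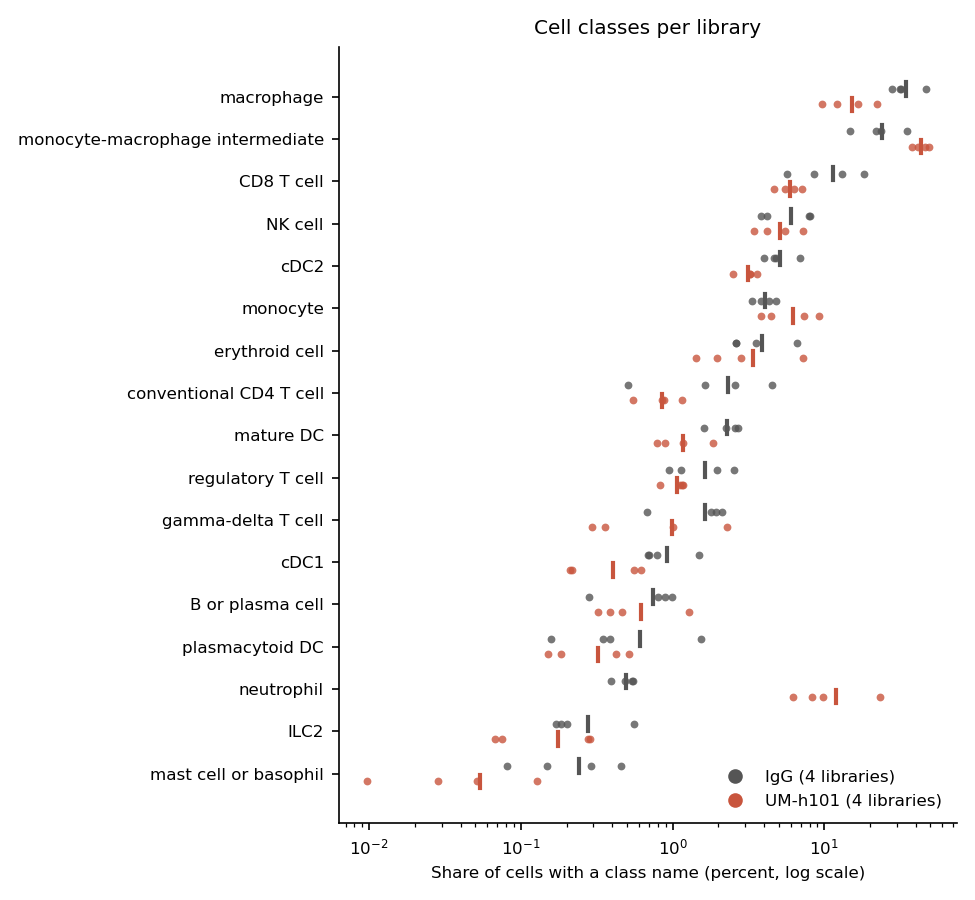
Share of each class among cells with a class name (percent, log scale) in 4 IgG and 4 UM-h101 libraries; points are libraries and bars are group means. Neutrophil shares lie between 6.23 and 23.4% in UM-h101 libraries, above all IgG libraries.

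The second comparison asks which genes differed within each class, from UMI counts summed per library and class and tested with edgeR. Intermediates had the most, with 3768 of 15932 genes passing, 2194 higher and 1574 lower in UM-h101 libraries. CD8 T cells had 1150 of 11862 (897 higher, 253 lower), NK cells 658 (487 and 171), macrophages 601 (376 and 225), monocytes 567 (461 and 106) and cDC2 467 (402 and 65). Neutrophils had 203 (171 and 32), mature dendritic cells 170 (138 and 32), regulatory T cells 63 (55 and 8), conventional CD4 T cells 47 (36 and 11), gamma-delta T cells 34 (33 and 1) and cDC1 20 (18 and 2). B or plasma cells had 1 passing gene, Dand5, an extracellular antagonist of Nodal signalling (3.02 ± 0.42, adjusted p = 0.0327), which with 1 library left out passed only without IgG 3 or UM-h101 1. Among the highest risers of most classes were genes counted at under 10 CPM in IgG libraries.

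**Figure D2:**
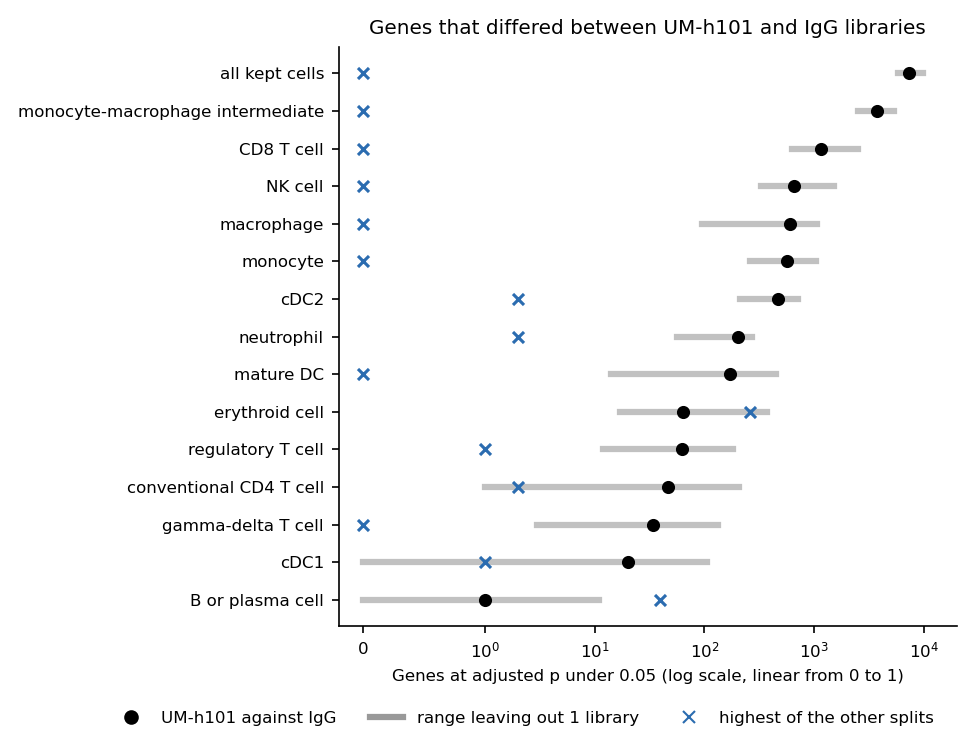
Number of genes at adjusted p under 0.05 per class (log scale, linear from 0 to 1): circles give UM-h101 against IgG, grey bars the range when each library is left out in turn, and crosses the highest count among the other ways of splitting the 8 libraries 4 against 4. The circle lies above the cross in all classes except B or plasma cells and erythroid cells.

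CD8 T cells of UM-h101 libraries had less RNA for several inhibitory and dysfunction-linked genes. Pdcd1, which encodes the inhibitory receptor PD-1, fell from 384 ± 149 to 181 ± 30.1 CPM (-1.08 ± 0.25, adjusted p = 0.026). Its IgG mean was raised by IgG 3, at 606 CPM against 287.5 to 325 CPM in the other IgG libraries. Tox, a transcription factor of exhausted T cells, fell from 858 ± 54.2 to 440.3 ± 129 CPM (-0.96 ± 0.23, adjusted p = 0.0268). Cd244a, which encodes the receptor 2B4, fell by 0.74 on the log2 scale (adjusted p = 0.0181). Of the 18 members of the exhaustion list, 4 fell and none rose, with the same count adjusted over the list alone, and the list passed as lower (camera adjusted p = 0.0313; 0.826 with an estimated correlation). Tnf, the ligand of TNFR2, rose from 33 ± 9.02 to 72.8 ± 15.9 CPM (1.14 ± 0.23, adjusted p = 0.0142). These calls rest on few libraries: Pdcd1 had adjusted p = 0.0871 without UM-h101 4, Tox 0.0805 without UM-h101 3 and Tnf 0.0602 without UM-h101 3. The exhaustion list had 0.0559 without IgG 4 and 0.107 without UM-h101 4. With the share of ribosomal protein UMIs as a covariate the fall of Pdcd1 shrank to -0.64 ± 0.18 (adjusted p = 0.0335). That share was 10.332 to 18.268% of a median CD8 T cell in IgG and 8.138 to 10.263% in UM-h101 libraries. It follows the group, so the covariate can take up part of a group difference.

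Neither TNF receptor gene passed in CD8 T cells: Tnfrsf1b was counted at 111 ± 25.6 and 102 ± 5.1 CPM (-0.13 ± 0.17, adjusted p = 0.643) and Tnfrsf1a had a log2 fold change of -0.16 ± 0.20. In mm10 (GRCm38) Tnfrsf1b (ENSMUSG00000028599) lies on chromosome 4 from 145213463 to 145246870 and Pdcd1 (ENSMUSG00000026285) on chromosome 1 from 94038305 to 94052553. The effector genes Gzmb, Prf1 and Ifng in CD8 T cells, which encode granzyme B, perforin and interferon gamma, had log2 fold changes of -0.25 ± 0.34, -0.30 ± 0.28 and -0.00 ± 0.46 and did not pass. Gzmb lay at 1550 CPM in IgG 3 against 555.8 to 708.5 CPM in the other IgG libraries. Ifng lay at 656 CPM in IgG 3 against 126 to 216 CPM in the other IgG libraries. Without IgG 3 it rose by 0.79 on the log2 scale (adjusted p = 0.00824). The cytotoxic effector list did not pass (adjusted p = 0.18), with 2 members higher and 1 lower, or 3 and 1 adjusted over the list alone. Havcr2, Ctla4, Il2ra and Tcf7 had log2 fold changes of 0.11, -0.38, 0.45 and 0.55 without passing, and Foxp3 was too low to be tested.

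In CD8 T cells Arg1 and Arg2, which encode the 2 arginases, rose by 1.47 ± 0.35 and 1.56 ± 0.34 (adjusted p = 0.0296 and 0.0196), and Nos2, inducible nitric oxide synthase, by 2.33 ± 0.37 (adjusted p = 0.00428). The arginine importer gene Slc7a1 (-0.57 ± 0.16) and the polyamine enzyme gene Odc1 (-0.42 ± 0.17) did not pass, and neither did the arginine and polyamine list (adjusted p = 0.699; 3 members higher and 1 lower, or 4 and 3 adjusted over the list alone). Arg2 was counted at only 3.31 ± 1.44 and 9.43 ± 2.25 CPM and Nos2 at 0.921 ± 0.366 and 4.7 ± 1.33 CPM. In UM-h101 libraries the level in CD8 T cells was 3.31% of that in all kept cells for Arg1, 3.72% for Nos2 and 7.88% for Arg2, beside 3.17 to 7.23% for 9 macrophage genes that T cells should lack. Arg1 had adjusted p = 0.0943 and Arg2 0.0723 without UM-h101 3, whereas Nos2 passed without each library in turn.

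Some immediate-early genes, which switch on within minutes of a stimulus or of tissue handling, were higher in CD8 T cells of UM-h101 libraries, and some mitotic genes were lower. Fos, Fosb and Atf3, which encode transcription factors of that early response, rose by 1.10 ± 0.25, 0.89 ± 0.22 and 1.12 ± 0.26. Their list of dissociation and stress genes had 4 of 19 members higher and none lower, or 7 and none adjusted over the list alone (adjusted p = 0.00908; 0.826 with an estimated correlation), and did not pass without IgG 4 (adjusted p = 0.159). Cenpa, Plk1 and Top2a, which act in chromosome segregation, fell by 1.18, 1.21 and 0.68 on the log2 scale. With the share of ribosomal protein UMIs as a covariate Cenpa fell by 0.64 and still passed, and Plk1 by 0.58 without passing (adjusted p = 0.0802); without IgG 3 Plk1 fell by 0.79 and passed. Cenpa lay at 407 CPM in IgG 3 against 177 to 197 CPM in the other IgG libraries. Of the 30 cell cycle genes, 4 fell and none rose, or 18 and none adjusted over the list alone (adjusted p = 1.06e-06; 0.826 with an estimated correlation). The 6 lists that passed in CD8 T cells all lost the call with an estimated correlation (adjusted p = 0.826 to 0.889 with an estimated correlation). They include nuclear-encoded oxidative phosphorylation genes and cytosolic ribosomal protein genes, with median log2 fold changes of -0.49 and -0.44 and no member past the threshold. Without IgG 3 the first had a median of 0.01 (adjusted p = 0.873). Ribosomal protein UMIs made up 18.3% of a median CD8 T cell in IgG 3 and 8.14 to 12.5% in the other 7 libraries.

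Some of the genes with the largest falls in CD8 T cells are known from connective tissue and tumour cells. They were picked by the size of their fall, which does not test such genes as a set. The tumour, fibroblast and endothelial list was not among the lists that passed in CD8 T cells, and passed as lower in only 1 of 9 fits. Sparc, a matrix glycoprotein, fell by 2.35 on the log2 scale, Serpinh1, the collagen chaperone HSP47, by 2.14, Cavin1, a coat protein of caveolae, by 2.79, and Zfpm2, a cofactor of GATA factors, by 2.47. The falls of these 4 genes were not particular to CD8 T cells. Sparc fell in 6 of 7 classes tested, Serpinh1 in 7 of 8, Cavin1 in 4 of 5 and Zfpm2 in 7 of 7. The fraction of cells low in Ptprc was also lower, at 17.4 ± 5.05% in IgG and 2.88 ± 0.594% in UM-h101 libraries. Whether RNA from other cells accounts for the falls was not tested. Tmem273, Galnt18, Hmga2, Epdr1, Tmcc3 and Tcrg-C2, a constant segment of the gamma-delta T-cell receptor, fell by 1.99 to 2.58. The largest rises began from low levels: Trpm6, a magnesium channel, rose by 5.29 ± 0.71, Rtbdn, retbindin, by 4.81 ± 0.57, Itgb4, integrin beta 4, by 3.80 ± 0.45 and Mpo, the myeloperoxidase of granulocytes, by 3.80 ± 0.36. BC051537, Syt16, Fam71a, Tomm20l, Ppp1r36 and Efna2, ephrin-A2, rose by 3.38 to 3.69. These rises were not particular to CD8 T cells. BC051537 rose in 8 of 8 classes tested, Syt16 in 6 of 6, Fam71a in 5 of 8, Tomm20l in 5 of 5, Ppp1r36 in 6 of 7 and Efna2 in 8 of 12. Neutrophil genes rose too, S100a9 by 3.31 ± 0.65 and Acod1, which makes itaconate, by 1.31 ± 0.33. Of 3 tested members of the neutrophil list 2 were higher, or 3 adjusted over the list alone (adjusted p = 0.00908; 0.826 with an estimated correlation), beside a 24.2-fold higher neutrophil share. The count filter admits genes high in 1 group alone, so calls of this list decide little. Of 35 passing genes the naming rule picked here, 18 passed without each library in turn and 30 with the covariate. Of the other 5, Plk1 halved as given above and Tcrg-C2 went from -1.99 ± 0.47 to -1.36 ± 0.48, while Arg1 (1.21 ± 0.41), Fos (0.94 ± 0.29) and Acod1 (1.12 ± 0.39) kept most of their fold. The count of 1150 became 2506 without IgG 3, 627 without UM-h101 3 and 656 without UM-h101 4. The groups fill the class from different clusters, since 1 cluster held 4.64% of its cells in IgG and 56.1% in UM-h101 libraries and another, 95.1% from IgG 3, held 25.04 and 0.27%.

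**Figure D3:**
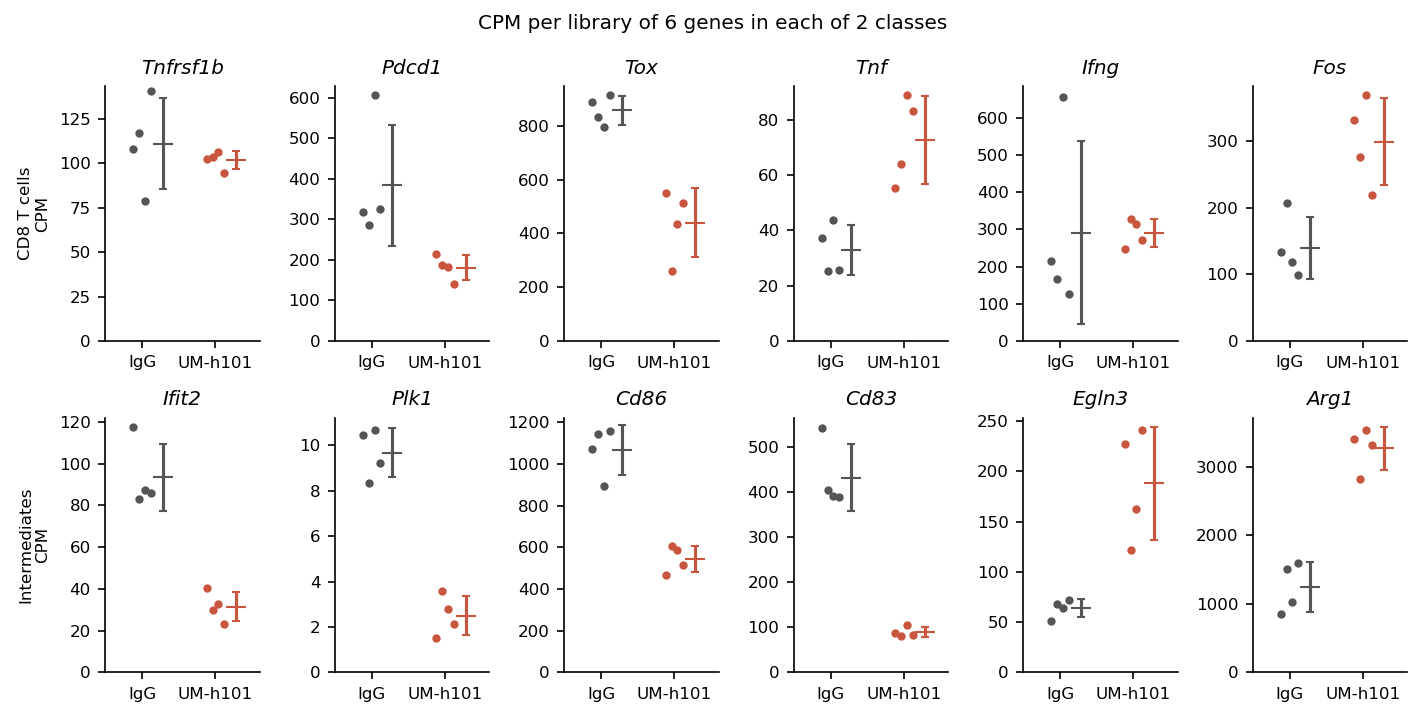
Level (CPM) of 6 genes in CD8 T cells (top) and of 6 genes in intermediates (bottom), with 1 point per library for 4 IgG and 4 UM-h101 libraries and the mean ± SD beside the points. Pdcd1 and Tox in CD8 T cells and Ifit2, Plk1, Cd86 and Cd83 in intermediates lie lower in all 4 UM-h101 libraries than in all 4 IgG libraries, and Ifng in IgG 3 lies apart.

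In regulatory T cells neither Foxp3, the factor that defines the lineage, nor the gene of TNFR2 differed between the groups by the test, while Pdcd1 fell. Foxp3 was counted at 278 ± 53.9 and 298 ± 24.9 CPM (0.10 ± 0.18), Tnfrsf1b at 159 ± 45.8 and 157 ± 17.5 CPM (-0.02 ± 0.22), and neither passed. Il2ra, the receptor of interleukin 2 (0.59 ± 0.20, adjusted p = 0.239), Ctla4 (-0.15 ± 0.24), Tnf (1.05 ± 0.27, adjusted p = 0.0967) and Ifng (1.31 ± 0.72) did not pass either. Pdcd1 fell from 97.3 ± 39.4 to 37.9 ± 2.07 CPM (-1.37 ± 0.28, adjusted p = 0.0371). Nt5e, which encodes the adenosine-producing enzyme CD73, fell by 1.08 on the log2 scale, Bcl2, a survival factor, by 1.16, the chemokine gene Ccl5 by 1.95 (1.13 without IgG 3) and Plac8 by 1.77. Gramd3 and Hacd3 fell by 1.34 and 0.99. C1qa, a complement gene of macrophages, fell by 2.18. The macrophage list had 1 of 8 members lower, or 6 adjusted over the list alone (adjusted p = 0.000528; 0.527 with an estimated correlation), beside a macrophage share of 34.6 ± 8.36% in IgG and 15.1 ± 5.45% in UM-h101 libraries. Genes that rose were counted at 5.06 to 29.6 CPM in IgG libraries: Cacna1f, a calcium channel, Syt16, Efna2, Soga1, Il22ra2, a soluble receptor that binds interleukin 22, Pde4c, Chrna9, Tmprss6, C1qtnf9 and Asah2, by 2.17 to 2.99 on the log2 scale. Most of these rises were not particular to regulatory T cells. Syt16 rose in 6 of 6 classes tested, C1qtnf9 in 6 of 7, Il22ra2 in 7 of 9, Efna2 in 8 of 12 and Pde4c in 6 of 13. Soga1 rose in 3 of 11 and Cacna1f in 1 of 3. Arg2, Nos2 and Tcf7 were too low to be tested in regulatory T cells.

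No gene of arginine use and no effector gene tested passed in regulatory T cells, with Arg1 at 0.78 ± 0.43, Slc7a1 at -0.31 ± 0.19, Odc1 at -0.46 ± 0.18, Gzmb at -0.03 ± 0.39 and Prf1 at -1.05 ± 0.58. Tox, Havcr2 and Tnfrsf1a had log2 fold changes of -0.01, 0.24 and -0.06. The 5 lists that passed were all lower and all lost the call with an estimated correlation (adjusted p = 0.527 to 0.676 with an estimated correlation). Only Syt16 and Pde4c among 18 named passing genes held without each library in turn, and both also rose in other classes. Without UM-h101 4 the other 16 did not pass (adjusted p up to 0.190). The count of 63 became 27 without IgG 1, 31 without IgG 2, 183 without IgG 3, 18 without UM-h101 1, 28 without UM-h101 3 and 12 without UM-h101 4.

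In NK cells, the innate killers, Ctla4 fell from 117 ± 25.3 to 35.6 ± 10 CPM (-1.73 ± 0.24, adjusted p = 0.00252), Icos, a costimulatory receptor, fell by 1.76 and Cd274, which encodes PD-L1, by 0.80 on the log2 scale. Itgae, the integrin CD103 that binds epithelium, rose by 1.94 ± 0.35. Ctla4, Icos and Itgae belong to the regulatory T-cell list, of whose 18 tested members 3 fell and 1 rose, or 7 and 1 adjusted over the list alone (adjusted p = 0.000655; 0.573 with an estimated correlation). The mitotic genes Cenpa, Ccnb1 and Top2a fell by 1.03, 1.58 and 0.79 (cell cycle list: 3 of 30 lower and none higher, or 8 and 1 adjusted over the list alone, adjusted p = 1.11e-05, 0.757 with an estimated correlation), and Fos and Zfp36, an mRNA decay factor, rose by 0.91 and 1.06. Arg2 rose by 1.41 ± 0.29 from 3.41 ± 1 CPM, while over all kept cells it rose from 29.9 to 130 CPM, so RNA from other cells was not ruled out here, and Slc7a1 fell by 0.66. Serpina3g, a target of interferon gamma, fell by 1.20 (0.72 without IgG 3) and Trbc1, a T-cell receptor constant gene, by 0.86. Some genes known from connective tissue fell here as well: Serpinh1 by 3.16, Timp3 by 3.35, Zfpm2 by 3.30, Tm4sf1 by 3.26, Sparc by 2.83, Col3a1 by 1.94 and the endothelial gene Ly6c1 by 3.57. Across fits the tumour, fibroblast and endothelial list passed as lower in only 1 of 9. Cxcl3, a neutrophil-attracting chemokine, rose by 4.54 ± 0.57 from 0.426 CPM, and Tomt, Tomm20l, Ppp1r36 and Tex14 rose by 3.00 to 4.26. Such rises were not particular to NK cells, since Cxcl3 rose in 7 of 8 classes tested, Tomt in 5 of 6 and Tex14 in 11 of 14.

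All 8 lists that passed in NK cells lost the call with an estimated correlation (adjusted p = 0.573 to 0.757 with an estimated correlation). Of 25 named passing NK genes 14 held without each library in turn, Ctla4, Icos, Itgae and Cenpa among them. The count of 658 became 429 without IgG 1, 1525 without IgG 3, 355 without UM-h101 1, 423 without UM-h101 3 and 325 without UM-h101 4. In this class 1 cluster held 5.11% of cells in IgG and 69.7% in UM-h101 libraries while another, 93.6% from IgG 3, held 23.03 and 0.27%.

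In conventional CD4 T cells Pdcd1 fell from 197 ± 71.3 to 75.8 ± 17.2 CPM (-1.41 ± 0.28, adjusted p = 0.0368). Ccr7, the lymph-node homing receptor, fell by 2.81 on the log2 scale, the calmodulin-binding gene Nrgn by 3.36, the phosphatase gene Dusp14 by 2.07, the NK receptor gene Klre1 by 1.99 and Serpinb6b by 1.75. BC051537, Il22ra2, Rtbdn, Rnaseh2a, a subunit of ribonuclease H2, and Glb1l rose by 2.28 to 2.70. Of 15 exhaustion genes 1 fell, also adjusted over the list alone (adjusted p = 0.00549; 0.699 with an estimated correlation and 0.0572 without IgG 2). In gamma-delta T cells Cx3cr1, the receptor of fractalkine, rose by 1.86 ± 0.35, and 1 of 14 cytotoxic effector genes was higher, or 3 adjusted over the list alone (adjusted p = 0.00234; 0.75 with an estimated correlation and 0.347 without IgG 4). Ccl8, a monocyte-attracting chemokine, fell by 1.98, and Il22ra2, Astl, Rnaseh2a, Slc10a1, the bile acid importer of liver, and Sv2c rose by 2.16 to 2.79. None of the 11 named CD4 genes passed without UM-h101 4 and none of the 7 named gamma-delta genes without IgG 1. The counts of 47 and 34 ranged from 1 (without IgG 2) to 207 (without IgG 3) and from 3 (without IgG 1, IgG 4 or UM-h101 4) to 134 (without IgG 3).

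Neutrophils, the class that was most enriched in UM-h101 libraries, carried more RNA of several hypoxia-responsive and inflammatory genes there. P4ha1, a collagen prolyl hydroxylase, rose from 208 ± 77.3 to 688 ± 81.1 CPM (1.75 ± 0.29, adjusted p = 0.00266), Ero1l, an oxidase of the endoplasmic reticulum, by 1.66 ± 0.28 and Egln3, an oxygen-sensing prolyl hydroxylase, by 1.37 ± 0.25. Of 16 hypoxia genes 7 rose and none fell, or 12 and none adjusted over the list alone (adjusted p = 2.13e-10), and this was the only one of 110 passing pairs of a class and a list that held with an estimated correlation (adjusted p = 0.02 with an estimated correlation). Nos2 rose by 3.05 ± 0.52 (adjusted p = 0.00359) and Spp1, osteopontin, by 1.50 ± 0.25. Both rose in other classes too, so RNA from other cells was not ruled out. Il1a, interleukin 1 alpha, rose by 1.35 ± 0.24 and Il23a, a subunit of interleukin 23, by 1.89 ± 0.37. Cd274 rose by 1.45, the glucose transporter Slc2a1 by 1.05 and Pfkfb3, an activator of glycolysis, by 1.58. Cd83, a marker of activated antigen-presenting cells, fell by 1.61, while Tnip1 and Traf1, NF-kB regulators, rose by 1.95 and 1.34. Pglyrp1, a granule protein, fell by 2.05, and Rab3d, Nedd4 and Mad2l1 by 2.04, 2.35 and 2.36.

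The inflammatory myeloid list had 3 of 20 members higher and none lower in neutrophils, or 5 and none adjusted over the list alone (adjusted p = 0.000993; 0.31 with an estimated correlation). The TNF and NF-kB list had 2 higher and 1 lower of 27, or 6 and 1 (adjusted p = 0.000599; 0.486 with an estimated correlation), and the glycolysis list 2 of 17 higher, or 4 (adjusted p = 0.00029; 0.368 with an estimated correlation and 0.0541 without UM-h101 4). Apart from hypoxia, the lists that passed in this class lost the call with an estimated correlation (adjusted p = 0.31 to 0.864 with an estimated correlation). Genes without a UMI in IgG neutrophils were higher in UM-h101 libraries, measured against 3 UMIs over the IgG group: BC051537 at least 4.52-fold, Kif24, a kinesin, at least 3.17-fold and Hal, histidine ammonia-lyase, at least 2.88-fold. Agbl3 and Tmco6, with 1 UMI each in the IgG group, had ratios of 17.2 (3.07 to 679) and 12.8 (2.28 to 505) with 95% counting intervals in brackets. The IgG side of this comparison is thin, with 30 to 93 cells and at least 78581 UMIs per library. Serpinh1 fell by 2.98, Ifi35, an interferon-induced gene, by 1.34 (0.86 without IgG 3, adjusted p = 0.248) and Cenpa by 1.47. The count of 203 became 56 without UM-h101 1, 64 without UM-h101 2 and 57 without UM-h101 3. Those fits also tested far fewer genes, so the lower counts do not by themselves show dependence on a single library. Of 25 named genes 11, with P4ha1, Ero1l, Egln3, Nos2, Il1a, Il23a, Spp1 and Cd83 among them, held without each library in turn. With the share of ribosomal protein UMIs as a covariate only 1 gene passed. That share itself parted the groups, at 2.156 to 4.114% of a median neutrophil in IgG and 1.649 to 2.14% in UM-h101 libraries. The fit can therefore hardly tell the covariate from the group, and the lost calls decide little.

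Intermediates of UM-h101 libraries had lower proliferation, interferon-response and antigen-presentation RNA and higher RNA of some hypoxia-response genes than those of IgG libraries. Of 30 cell cycle genes 25 fell and none rose (26 and 1 adjusted over the list alone), led by Plk1, a mitotic kinase (-1.94 ± 0.24, adjusted p = 0.000758), Rrm1, a subunit of ribonucleotide reductase (-0.96 ± 0.12), and Ccna2, cyclin A2 (-1.83 ± 0.24). Of 27 type I interferon response genes 20 fell and none rose (26 and none adjusted over the list alone): Ifit2 fell from 93.5 ± 16 to 31.6 ± 7.05 CPM (-1.57 ± 0.18, adjusted p = 0.000644), Ifit3b by 2.21 and Ifi44 by 1.65. Of 15 class II presentation genes 7 fell and none rose (13 and none adjusted over the list alone), among them the costimulatory genes Cd86 (-0.97 ± 0.15) and Cd80 (-0.59 ± 0.14) and H2-Ob (-1.34 ± 0.24), part of a chaperone of class II loading. Of 19 hypoxia genes 6 rose and none fell (8 and none adjusted over the list alone), with Egln3 at 1.56 ± 0.22, Ddit4, an inhibitor of mTORC1, at 0.92 ± 0.18 and P4ha1 at 0.65 ± 0.13. These 4 lists passed camera with adjusted p = 1.09e-14, 7.72e-13, 6.18e-05 and 0.0006, and gave adjusted p = 0.378, 0.378, 0.498 and 0.498 with an estimated correlation.

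**Figure D4:**
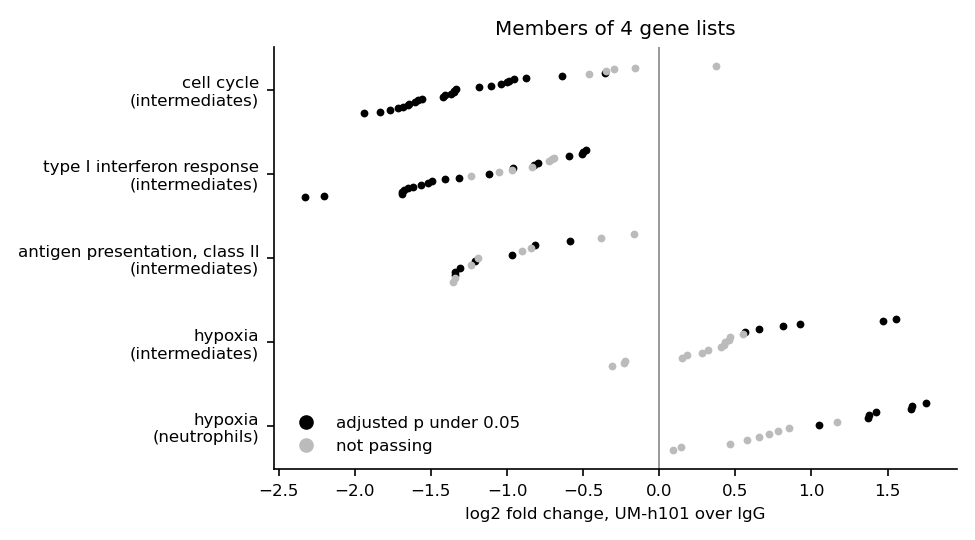
log2 fold change of UM-h101 over IgG for each tested member of 4 gene lists in intermediates and of the hypoxia list in neutrophils; black points passed at adjusted p under 0.05 and grey points did not. Passing cell cycle, interferon and class II members lie below 0 and passing hypoxia members above 0.

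Some NF-kB targets and inflammatory cytokine genes also moved in intermediates. Cd83 fell from 432 ± 73.7 to 89.3 ± 10.7 CPM (-2.27 ± 0.16, adjusted p = 0.000126), and Rel and Nfkbie, an NF-kB subunit and an NF-kB inhibitor, fell by 1.05 and 0.70. Of 28 list members 7 fell and 1 rose, or 8 and 1 adjusted over the list alone (adjusted p = 0.00316; 0.28 with an estimated correlation). Il12b, the p40 subunit of interleukins 12 and 23, fell by 3.30, Il15 by 0.77 and Gbp2b and Gbp5, interferon-inducible GTPases, by 3.95 and 0.73, whereas Il12a, the p35 subunit, rose by 3.77 ± 0.73 from 0.047 CPM. The inflammatory myeloid list had 8 lower and 2 higher of 22, or 8 and 3 adjusted over the list alone (adjusted p = 0.0149; 0.324 with an estimated correlation). The interferon-gamma list had 6 lower and 1 higher of 24, or 6 and 1 (adjusted p = 0.0177; 0.682 with an estimated correlation, 0.105 without IgG 3, 0.0515 without IgG 2 and 0.063 without UM-h101 3). Arg1, also a marker used to name this class, rose by 1.39 ± 0.22, Nos2 by 1.25 ± 0.30 and Arg2 by 0.77 ± 0.18, while Slc7a1 and Odc1 fell by 0.62 and 0.54. Cx3cr1 fell by 0.95, Klrk1, the activating receptor NKG2D, by 1.45 and Serpina3g by 1.76 (1.16 without IgG 3); Id2, an inhibitor of E proteins, rose by 0.71. Pdcd1, Tox and Il2ra, counted at 1.42, 3.39 and 4.03 CPM in IgG libraries, fell by 1.91, 0.99 and 1.26, beside a CD8 T-cell share of 11.4% in IgG and 5.9% in UM-h101 libraries (exact permutation test, p = 0.0857), while T-cell genes read in this class did not pass as a list (adjusted p = 0.161), and Itgae and Ikzf4 rose by 1.54 and 1.73.

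The lists of T-cell and other-lineage genes gave further calls in intermediates: 7 of 24 cytotoxic effector genes fell and 2 rose (10 and 4 adjusted over the list alone; adjusted p = 0.041, 0.682 with an estimated correlation), 6 of 23 regulatory T-cell genes fell and 2 rose (9 and 2; adjusted p = 0.041, 0.498 with an estimated correlation), and 5 of 10 neutrophil genes rose (also 5; adjusted p = 0.0122, 0.498 with an estimated correlation), with S100a8 at 2.68 ± 0.33, Mmp9 at 2.35 ± 0.30 and S100a9 at 2.77 ± 0.66. The stress list (adjusted p = 0.048; 0.682 with an estimated correlation) had Ier2 and Hsph1 lower by 0.95 (0.59 without IgG 3) and 0.49 and Jun higher by 0.57. The largest other changes were BB123696, with 2 UMIs in the IgG group and a ratio of 18.3 (4.94 to 154) by counting, Ppp1r36, Tktl2 and Rnf182 (3.46, 3.39 and 3.36), and falls in Msln, mesothelin, Galnt18 and Tbx20 by 3.82, 3.28 and 3.15. All 15 lists that passed lost the call with an estimated correlation (adjusted p = 0.28 to 0.682 with an estimated correlation). Of 50 named genes 43 held without each library in turn, and the count of 3768 became 2510 without UM-h101 4. With the share of ribosomal protein UMIs as a covariate 1283 genes passed, 31 of the 50 named ones among them. That share was 8.14 to 11.144% in IgG and 6.884 to 8.25% in UM-h101 libraries, so the covariate closely follows the group. Some calls ended with about the same fold and a wider error, such as Slc7a1 (-0.62 ± 0.16 and -0.62 ± 0.22), Odc1 (-0.54 ± 0.13 and -0.55 ± 0.18), Gbp5 (-0.73 ± 0.17 and -0.74 ± 0.23) and Arg2 (0.77 ± 0.18 and 0.72 ± 0.26). For others the fold shrank, as for Nos2 (1.25 ± 0.30 and 0.59 ± 0.28), Ier2 (-0.95 ± 0.27 and -0.22 ± 0.22) and Pdcd1 (-1.91 ± 0.39 and -1.19 ± 0.50). In this class 1 cluster held 5.79% of intermediates in IgG and 42.8% in UM-h101 libraries and another 41.0 and 16.4%, while a cluster led by type I interferon response genes held 14.04 and 5.68%.

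Macrophages showed the fall of Cd83 (-1.94 ± 0.17, adjusted p = 0.00262) and of some other NF-kB targets in UM-h101 libraries. Of 28 TNF and NF-kB targets 7 fell and 1 rose, or 14 and 2 adjusted over the list alone (adjusted p = 5.08e-06; 0.208 with an estimated correlation), with Nfkbiz, an NF-kB cofactor, lower by 0.89, Il1b, interleukin 1 beta, by 0.92, Cxcl1, a neutrophil attractant, by 1.09 and its relative Cxcl3 higher by 2.14. Cx3cr1 fell by 1.00, Cd80 by 0.68 and Ier2 by 1.05, and Slc7a1 and Odc1 fell by 0.77 and 0.72, while Arg1, a marker of the class, rose by 1.16. Timd4, a receptor of resident macrophages for dying cells, fell by 5.05. Haemoglobin genes fell most, Hbb-bs by 6.25, Hba-a2 by 6.16, Hba-a1 by 5.59 and Hbb-bt by 5.46, that is all 4 erythroid genes tested (adjusted p = 5.08e-06; 0.302 with an estimated correlation). Neutrophil genes rose, 3 of 8, or 5 adjusted over the list alone (adjusted p = 0.000213; 0.302 with an estimated correlation), with S100a8 at 2.28 ± 0.33, Mmp9 at 1.77 ± 0.28 and G0s2 at 2.31 ± 0.51. H2-M2, a non-classical class I gene, Gipr, Orm1, Adam22 and Cstdc4 rose by 2.72 to 3.66 from 0.0545 to 2.50 CPM; Cstdc4 has near-identical relatives among which reads cannot be placed with certainty. Pdcd1 and Cd3g fell by 2.17 and 1.68, with T-cell genes read in this class lower as a list (adjusted p = 0.00978; 0.623 with an estimated correlation), and Cd4 rose by 1.17.

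The 12 lists that passed in macrophages lost the call with an estimated correlation (adjusted p = 0.208 to 0.834 with an estimated correlation). The count of 601 became 95 without IgG 1, 224 without IgG 2, 1066 without IgG 3, 127 without UM-h101 1, 384 without UM-h101 3 and 171 without UM-h101 4. Passing without each library in turn were 10 of 27 named genes, with Cd83, Cxcl3, Timd4, S100a8 and the 4 haemoglobin genes among them. With the share of ribosomal protein UMIs as a covariate 34 genes passed, 31 of them among the 601. That share was 7.34 to 12.063% in IgG and 5.552 to 8.338% in UM-h101 libraries, so the covariate partly follows the group. The 3 clusters of this class held 43.2, 41.7 and 15.1% of its cells in IgG and 56.0, 18.5 and 25.6% in UM-h101 libraries, so its changes also mix clusters.

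Monocytes of UM-h101 libraries had more Spp1 (1.79 ± 0.25, adjusted p = 0.00288), Arg1 (1.54 ± 0.33) and Tnf (0.60 ± 0.15) and less Cd83 (-1.23 ± 0.18) and Rel (-0.77 ± 0.18). Oas3, an antiviral enzyme, fell by 0.73, the only one of 24 type I interferon genes to pass, or 1 of 5 that fell adjusted over the list alone (adjusted p = 8.45e-05; 0.63 with an estimated correlation). Serpinh1, Zfpm2, Cdh13, an atypical cadherin of vessels, Igfbp6 and Pclaf, a partner of PCNA in DNA replication, fell by 2.78, 2.70, 2.65, 2.31 and 2.10. Serpinh1 fell in 7 of 8 classes tested, Zfpm2 in 7 of 7, Cdh13 in 5 of 6, Igfbp6 in 4 of 5 and Pclaf in 2 of 13. The falls of the first 4 were thus not particular to monocytes, and RNA from other cells was not ruled out here. Ppm1n, Smim41 and Vmn2r19 had 1 to 3 UMIs in the IgG group and ratios of 73.7 (13.1 to 2926), 18.1 (6.07 to 88.8) and 16.2 (5.4 to 79.4) with 95% counting intervals. BC051537 and Rtbdn rose by 4.25 and 3.90. All 6 lists that passed lost the call with an estimated correlation (adjusted p = 0.63 to 0.946 with an estimated correlation). The count of 567 became 259 without IgG 1, 1037 without IgG 3, 322 without UM-h101 1 and 332 without either UM-h101 3 or UM-h101 4. Of the named genes 12 of 16, Spp1, Cd83 and Oas3 included, held without each library in turn. Tnf did not without UM-h101 3 (adjusted p = 0.106).

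Genes lower in dendritic cells of UM-h101 libraries included a cytokine gene in cDC1 and some chemokine and activation genes in cDC2. In each dendritic class tested, more genes passed as higher than as lower. In cDC1 Il12b fell from 108 ± 57.2 to 6.04 ± 5.8 CPM (-4.42 ± 0.61, adjusted p = 0.0181). Bcl2l14, a relative of the BCL2 family, fell by 1.76, and Gsto2, Enthd1, Nfe2l3, Nckap5l and Gng4 rose by 2.08 to 3.34. In cDC2 Cd83 fell by 1.28, the chemokine genes Ccl7, Ccl6 and Cxcl1 by 1.35, 1.00 and 0.88 and Nfkbiz by 0.76. Of 28 NF-kB targets 3 fell and 1 rose, or 4 and 1 adjusted over the list alone (adjusted p = 0.00808; 0.315 with an estimated correlation). Nos2 and Arg1 rose in cDC2 by 2.23 ± 0.37 and 1.31 ± 0.28. Both also rose over all kept cells, so RNA from other cells was not ruled out here. The mitotic genes Cenpa and Tpx2 and the thymidine kinase gene Tk1 fell by 0.77, 0.82 and 0.85. Cd14 and Ctsd, read as macrophage genes, fell by 0.83 and 0.81, S100a8 rose by 2.96 (2.08 without UM-h101 4, adjusted p = 0.0708), and Tm4sf1, Serpinh1, Crip2, Zfpm2 and Chrm3 fell by 2.11 to 2.85. Ppp1r36, Gdpd4, Tomt and Prph, peripherin of neurons, rose by 3.02 to 3.26 from 0.546 to 1.84 CPM. In mature dendritic cells Bcl2l14 fell by 1.73, Cd81, a tetraspanin, by 2.07, Cd70, the ligand of CD27, by 1.95, and Sod3, extracellular superoxide dismutase, by 2.73. Cldn11, Gxylt2, Casr, the calcium-sensing receptor, Btnl2 and Eldr rose by 2.51 to 3.02. C1qb and C1qc fell there by 1.72 and 1.53.

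The lists that passed in dendritic cells lost the call with an estimated correlation (adjusted p = 0.681 in cDC1, 0.315 to 0.693 in cDC2 and 0.929 in mature dendritic cells with an estimated correlation). In cDC1 no named gene passed without IgG 1, and the count of 20 became 0 by edgeR without IgG 1, UM-h101 3 or UM-h101 4 (545, 571 and 525 genes at an unadjusted p under 0.05; DESeq2 on all libraries gave 71), 10 without IgG 2, 5 without UM-h101 1 and 106 without IgG 3. The count of 467 in cDC2 became 209 without IgG 1, 250 without IgG 2, 261 without UM-h101 1, 280 without UM-h101 3, 244 without UM-h101 4 and 714 without IgG 3. Of 22 named cDC2 genes 9 held without each library in turn (Cd83, Ccl7, Nos2, Tm4sf1, Serpinh1, Ppp1r36, Gdpd4, Tomt and Prph). The count of 170 in mature dendritic cells became 14 without IgG 1 and 26 to 76 without IgG 2 or any 1 UM-h101 library, and 453 without IgG 3, and of 11 named genes only Bcl2l14, Gxylt2 and Eldr held without each library in turn.

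In 11 of 14 classes 1 set of genes, summed, lay higher in all UM-h101 than in all IgG libraries: genes that lie just behind an abundant gene on the same strand. Their median log2 fold change was 0.55 in CD8 T cells but 0.05 in B or plasma cells and -0.01 in erythroid cells. Dnajb14, an endoplasmic reticulum co-chaperone that starts 753 bases after the end of H2afz, rose in 12 of 14 classes, Rnaseh2a, 4717 bases after Junb, in 9, Fbxl18, 7694 bases after Actb, in 9 and Trim69, 7617 bases after B2m, in 9. In CD8 T cells the 399 genes that start within 10 kb after the end of an abundant gene summed to 7615 ± 371 CPM in IgG and 10055 ± 555 CPM in UM-h101 libraries (exact permutation p = 0.0286, all 4 UM-h101 libraries above all IgG libraries). The 310 genes that end within 10 kb before the start of an abundant gene summed to 8185 ± 493 and 7892 ± 318 CPM (exact permutation p = 0.4). Such downstream genes made up 28.6% of the 56 genes that rose in at least 7 classes and 1.29% of the 8133 that rose in none and none of the 38 that fell in at least 4, counting genes tested in at least 7 classes. The 422 genes that face the end of an abundant gene from the other strand rose less, from 5389 ± 95.8 to 6109 ± 380 CPM in CD8 T cells (exact permutation p = 0.0286). Of the 897 genes that rose in CD8 T cells 89 were downstream genes, as was 1 of the 253 that fell. Fam71a in CD8 T cells (behind Atf3), Rnaseh2a in CD4 and gamma-delta T cells, Gng4 in cDC1 (behind Lyst) and Agbl3 in neutrophils (behind Cald1) are named above and belong to this set, as does Ifi35 (behind Rpl27), which fell in neutrophils. Abundance was judged over all kept cells, where Cald1 was at 188.5 CPM, so a neighbour need not be abundant in the class named. Only 16 of the 56 genes that rose in at least 7 classes were downstream genes, so most such genes lie outside this set. Of those named above, Astl rose in 11 of 13 classes tested, Tex14 in 11 of 14, Nfe2l3 in 10 of 13 and BC051537 in 8 of 8. Such a rise, given for 1 class, is not particular to it, and its cause was not tested. Malat1, a nuclear RNA, made up 1.25 to 1.54% of the UMIs of a median CD8 T cell in UM-h101 libraries, 0.900 to 1.05% in IgG 1, 2 and 4, and 0.463% in IgG 3. UMIs of 4 genes whose reads often come from ribosomal RNA (Gm42418, AY036118, Lars2 and Cmss1) made up 0.081% of a median CD8 T cell in IgG 3 and 0.754 to 1.295% in the other 7.

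**Figure D5:**
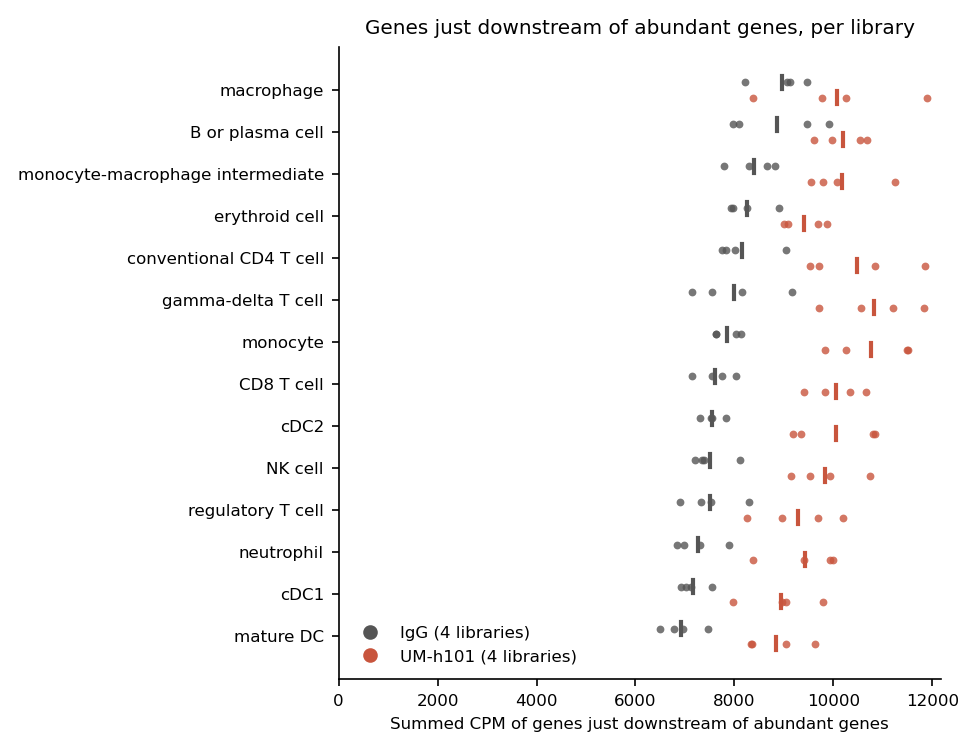
Summed level (CPM) of the 399 genes that start within 10 kb after the end of an abundant gene on the same strand, per class; points are the 4 IgG and 4 UM-h101 libraries and bars are group means. In 11 of 14 classes all UM-h101 libraries lie above all IgG libraries.

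Read across the 15 fits (14 classes and all kept cells), cytosolic ribosomal protein genes passed as lower in 15, nuclear-encoded oxidative phosphorylation in 12, cell cycle in 10, type I interferon response, macrophage genes and T-cell genes in 4 each (T-cell genes of 9 fits), class II presentation in 3, and exhaustion, regulatory T-cell and erythroid genes in 2 each (erythroid genes of 4 fits). Hypoxia genes passed as higher in 6, suppressive myeloid and neutrophil genes in 5 each (neutrophil genes of 8 fits), and T-cell activation and mitochondrially encoded oxidative phosphorylation in 1 each. Lists that went both ways were TNF and NF-kB targets (1 up, 4 down), inflammatory myeloid (2 up, 3 down), interferon-gamma response and cytotoxic effector (2 up and 2 down each), dissociation and stress (3 up, 3 down), chemokines (1 up, 2 down), glycolysis (2 up, 1 down) and TNF superfamily genes (1 up, 1 down). Mitochondrial upkeep and the tumour, fibroblast and endothelial list (of 9 fits) were lower in 1 each. Class I presentation, arginine and polyamine metabolism, naive and memory T-cell and B-cell genes (of 5 fits) passed in none by camera. Without IgG 3 the oxidative phosphorylation list (nuclear-encoded) changed its camera direction in 9 of its 12 fits, past the threshold only in monocytes (adjusted p = 0.0303), and in CD8 and NK cells it lost the call. Of 110 such calls 1 held with an estimated correlation, and other ways of splitting the 8 libraries gave up to 156 calls, so the number of list calls by itself is not evidence of an effect of treatment. In erythroid cells 64 of 7745 genes passed, 33 higher and 31 lower, and another split gave 258.

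Over all kept cells, where changes in composition and in expression mix, 7280 of 19985 genes passed, 3562 higher and 3718 lower. Arg1 rose from 510.3 ± 43 to 2277 ± 429 CPM (2.16 ± 0.18), Arg2 by 2.10 ± 0.16, Nos2 by 2.61 ± 0.26, Tnf by 1.07 ± 0.24 and Prok2, a chemoattractant made by neutrophils, by 6.15 ± 0.96. The stefin genes Csta3, Stfa2, Stfa2l1 and Cstdc4 rose, with 2 IgG UMIs and a ratio of 212 (58.2 to 1756) for Csta3, but these relatives are nearly identical in sequence. Slc7a1, Odc1 and Pdcd1 fell by 1.03, 0.91 and 1.43 (Pdcd1 by 0.83 without IgG 3), and Lyve1, a receptor of tissue macrophages and lymphatic vessels, Crabp1, Egr4, Adgra1 and the immunoglobulin gene Ighg2c fell by 3.40 to 7.04. Tnfrsf1b rose by 0.42 ± 0.15 and Havcr2 by 0.48 ± 0.16, but their adjusted p was 0.115 without IgG 1 and 0.109 without UM-h101 2. Pdcd1 did not pass without UM-h101 2, 3 or 4 (adjusted p = 0.055 to 0.066) or with the share of ribosomal protein UMIs as a covariate (-0.44 ± 0.44). That share parted the groups, at 8.797 to 13.598% of a median kept cell in IgG and 6.12 to 8.078% in UM-h101 libraries. The covariate fit therefore decides little here.

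The third comparison asks whether the 18 genes set in advance changed differently in CD8 T cells than in other classes. Of 234 differences between the effect in CD8 T cells and that in another class, none passed after adjustment by the exact permutation test, with 0.0286 as the smallest 2-sided p that 4 against 4 libraries can give and a smallest adjusted p of 0.257. Over 234 tests with that smallest p no single difference could have passed, so the outcome does not show that the effects were alike. An effect named above for 1 class is therefore not shown to be absent from, or different in, another.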

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

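The outlier test on each group of 4 was planned, while the reading of its results by library was made after they were seen. In 686 groups of 4 libraries a Dixon test set 1 library apart in 56, or 8.16%, where chance alone gives about 1 in 20, here 34.3. The groups of 1 gene are left out of these counts for a reason unrelated to its values. IgG 3 was the library set apart 25 times, UM-h101 4 10 times, IgG 4 6 times, IgG 1 5 times, UM-h101 1 4 times, and IgG 2, UM-h101 2 and UM-h101 3 2 times each. The genes were picked partly because they differed between groups, so the groups tested are not independent. Where the other 3 libraries have no count, any count sets the library apart, so such calls carry no weight. This holds for Cstdc4 in macrophages, Ppm1n in monocytes, and Agbl3 and Tmco6 in neutrophils, which are included in the counts above. Ranges give the other 3 libraries of the same group.

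In CD8 T cells IgG 3 lay apart for Ifng (656 CPM against 126 to 216), Gzmb (1550 CPM against 556 to 708), Pdcd1 (606 CPM against 288 to 325), Sdha (105 CPM against 67.1 to 73.6), Uqcrc2 (165 CPM against 56.4 to 59.1), Cenpa (407 CPM against 177 to 197). In NK cells IgG 3 lay apart for Tex14 (69.3 CPM against 21.9 to 27.5), Serpina3g (226 CPM against 80.7 to 98.8). In macrophages IgG 3 lay apart for Il1b (506 CPM against 283 to 303), Cd3g (7.2 CPM against 2.4 to 3.17). In mature dendritic cells IgG 3 lay apart for Cd81 (318 CPM against 126 to 137). In monocytes IgG 3 lay apart for Vmn2r19 (0 CPM against 0.445 to 0.525). In intermediates IgG 3 lay apart for Tktl2 (0 CPM against 0.098 to 0.105), Serpina3g (92.8 CPM against 25.8 to 31.6), H2-Ob (8.69 CPM against 4.61 to 4.84), C1qc (2043 CPM against 992 to 1010), C1qb (2504 CPM against 731 to 937). In neutrophils IgG 3 lay apart for Tmco6 (9.69 CPM against 0 to 0). In regulatory T cells IgG 3 lay apart for Ccl5 (835 CPM against 155 to 258), Tnf (51.4 CPM against 30.5 to 32). In all kept cells IgG 3 lay apart for Crabp1 (145 CPM against 32.3 to 49.8), Slc7a1 (98.7 CPM against 141 to 149.7). The share that set IgG 3 apart was ILC2 (0.556% against 0.171 to 0.202%), cDC1 (1.5% against 0.693 to 0.793%), plasmacytoid DC (1.53% against 0.157 to 0.384%).

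In NK cells UM-h101 4 lay apart for Arg2 (10.6 CPM against 8.17 to 8.44). In cDC2 UM-h101 4 lay apart for S100a8 (12.7 CPM against 2.79 to 3.46). In monocytes UM-h101 4 lay apart for Smim41 (14.7 CPM against 4.27 to 5.56), Vmn2r19 (9.17 CPM against 5.22 to 5.43). In intermediates UM-h101 4 lay apart for Il12b (0.483 CPM against 0.119 to 0.129), Id2 (598 CPM against 666 to 677), Ikzf4 (4.79 CPM against 3.31 to 3.41). In all kept cells UM-h101 4 lay apart for Stfa2 (1.66 CPM against 0.253 to 0.409), Havcr2 (46.4 CPM against 70.5 to 74.8). The share that set UM-h101 4 apart was cells low in Ptprc (3.77% against 2.54 to 2.62%).

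In CD8 T cells IgG 1 lay apart for Tmcc3 (69.2 CPM against 56.8 to 58.3). In macrophages IgG 1 lay apart for Cstdc4 (0.218 CPM against 0 to 0). In intermediates IgG 1 lay apart for Cd83 (542 CPM against 389 to 404), Ifit2 (117 CPM against 83.1 to 87.5). In neutrophils IgG 1 lay apart for P4ha1 (93.2 CPM against 233 to 261). In NK cells IgG 2 lay apart for Zfp36 (165 CPM against 73.2 to 79.3). In intermediates IgG 2 lay apart for Rnf182 (0.051 CPM against 0.098 to 0.105). In CD8 T cells IgG 4 lay apart for Top2a (304 CPM against 352 to 356). In macrophages IgG 4 lay apart for Hbb-bs (82.1 CPM against 19.8 to 24.7), Hba-a2 (26.8 CPM against 7.16 to 9.22), Hba-a1 (31.8 CPM against 8.88 to 12). In monocytes IgG 4 lay apart for Ppm1n (0.524 CPM against 0 to 0). In neutrophils IgG 4 lay apart for Agbl3 (6.21 CPM against 0 to 0). In erythroid cells UM-h101 1 lay apart for Tenm3 (7.73 CPM against 2.96 to 3.63). In macrophages UM-h101 1 lay apart for Orm1 (4.66 CPM against 1.99 to 2.1). In all kept cells UM-h101 1 lay apart for Ighg2c (0.204 CPM against 0 to 0.0187). The share that set UM-h101 1 apart was B or plasma cell (1.29% against 0.323 to 0.462%). In intermediates UM-h101 2 lay apart for Ddit4 (31.8 CPM against 50.3 to 52.9). The share that set UM-h101 2 apart was regulatory T cell (0.821% against 1.12 to 1.18%). In monocytes UM-h101 3 lay apart for Arg1 (1302 CPM against 795 to 805). In regulatory T cells UM-h101 3 lay apart for Tnfrsf1b (183 CPM against 146 to 149.9).

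The unassigned library lay above the IgG range for mature dendritic cells (2.79% against 1.61 to 2.71%) and for neutrophils (0.87% against 0.393 to 0.549%), and for neutrophils also below the UM-h101 range of 6.23 to 23.4%. It lay below the IgG range for gamma-delta T cells (0.237% against 0.68 to 2.11%), plasmacytoid dendritic cells (0.109% against 0.157 to 1.53%), ILC2 (0.148% against 0.171 to 0.556%) and mast cells or basophils (0.0593% against 0.0806 to 0.454%), for the first 2 also below the UM-h101 range.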

How the results depend on the processing

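Of the alternatives in this part, those with the ribosomal-protein share as covariate, without T and NK clusters mostly of 1 library, with the Ly6c2-led cluster, with other share denominators added later and without downstream genes were tests chosen after the result was seen. No paired analysis was possible because the replicate numbers only follow the order of deposit and tie no IgG library to a UM-h101 library.

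No share reached the threshold in any setting with all 8 libraries, and with 7 libraries shares were not tested. With 0.0286 as the smallest p and 17 classes, no class share could have passed on its own. This outcome therefore does not show that the class shares were alike or stable. Differences in shares changed sign 25 times, in 11 share results: NK cells, erythroid cells, B or plasma cells, plasmacytoid dendritic cells, regulatory T cells, each of the 4 T-cell classes as a share of T cells, the ratio of CD8 to regulatory T cells and the merged share. DESeq2 in place of edgeR gave 1878 genes in CD8 T cells, 1097 in NK cells, 104 in regulatory T cells, 102 in CD4 T cells, 59 in gamma-delta T cells, 1570 in macrophages, 860 in monocytes, 431 in neutrophils, 803 in cDC2, 71 in cDC1, 291 in mature dendritic cells, 60 in B or plasma cells and 124 in erythroid cells. On simulated changes its share of false calls in CD8 T cells was 16%. Without a filter on low counts the numbers were 1146 in NK cells, 375 in regulatory, 413 in CD4 and 153 in gamma-delta T cells, 1056 in monocytes, 522 in neutrophils, 126 in cDC1, 688 in mature dendritic cells, 175 in B or plasma cells and 348 in erythroid cells. With counts thinned to the smallest library they were 23 in regulatory, 21 in CD4 and 2 in gamma-delta T cells, 37 in neutrophils, 6 in cDC1, 93 in mature dendritic cells and 30 in erythroid cells, and 0 in B or plasma cells by edgeR (498 genes at an unadjusted p under 0.05). RLE size factors gave 12 in cDC1, doublets kept 17 in B or plasma cells, 88 in cDC1 and 287 in erythroid cells, and a resolution of 2 gave 1669 in macrophages. The stricter cell filter left B or plasma cells untested and gave counts close to those reported elsewhere.

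The ribosomal-protein share as covariate changed counts in both directions: 1890 genes in CD8 T cells, 1341 in NK cells, 154 in regulatory, 188 in CD4 and 120 in gamma-delta T cells, 896 in monocytes, 199 in cDC1, 260 in mature dendritic cells and 67 in B or plasma cells, but 1283 in intermediates, 34 in macrophages and 1 in neutrophils. All 25 named neutrophil genes lost their call though their folds kept their sign, with a median of 1.01 times the fold and 1.47 times the standard error of the fit without it; P4ha1 went from 1.75 ± 0.29 to 1.11 ± 0.36. Of 27 named macrophage genes 7 kept the call, Cd83 among them (-1.94 ± 0.17 and -1.82 ± 0.2), and the medians were 0.936 and 1.18 times. The calls ended mainly by wider errors, and for some genes, such as Il1b in macrophages (-0.92 ± 0.21 and -0.53 ± 0.2), by a smaller fold. In neutrophils, CD8 T cells and all kept cells the covariate was lower in every UM-h101 than in every IgG library. It came close to that in intermediates. Where it follows the group, the fit cannot separate it from treatment, so calls lost there decide little. Without T and NK clusters mostly of 1 library CD8 T cells had 1976 genes. Leaving out 1 library in turn gave 627 to 2506 genes in CD8 T cells, 325 to 1525 in NK cells, 12 to 183 in regulatory, 1 to 207 in CD4 and 3 to 134 in gamma-delta T cells, 95 to 1066 in macrophages, 2510 to 5352 in intermediates, 259 to 1037 in monocytes, 56 to 269 in neutrophils, 209 to 714 in cDC2, 0 to 106 in cDC1, 14 to 453 in mature dendritic cells, 0 to 11 in B or plasma cells and 17 to 371 in erythroid cells. Neutrophil fits without a UM-h101 library tested 2819 to 2877 genes in place of 8064. The CPM cutoff of the filter rises as the median depth falls, and that median is then the depth of a thin IgG library. Lower neutrophil counts in those fits thus also reflect fewer genes tested.

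The naming rule picked 283 passing genes, 9 of them in erythroid cells, whose changes are not given above. Of these 283, 279 of 279 tested passed with DESeq2, 277 of 283 with RLE size factors, 271 of 278 with the stricter filter, 254 of 272 at a resolution of 2, 251 of 282 with doublets kept, 274 of 283 without the filter on counts, 182 of 208 after thinning and 195 of 283 with the covariate. Leaving out a library kept 183 of 281 (IgG 1), 217 of 281 (IgG 2), 270 of 279 (IgG 3), 221 of 283 (IgG 4), 171 of 267 (UM-h101 1), 199 of 268 (UM-h101 2), 182 of 271 (UM-h101 3) and 165 of 270 (UM-h101 4). Ifng in CD8 T cells ran from -0.28 to 0.79 on the log2 scale with a library left out, the highest without IgG 3, and was 1.21 with the covariate.

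Of 110 list calls, 1 held with an estimated correlation, and fry by itself called 24 pairs, 21 of them among the 110. Without IgG 3, 75 held and 10 turned over by camera's direction, which can differ from the sign of the median. For nuclear-encoded oxidative phosphorylation 9 turned over, with conventional CD4 T cells at a median from -0.80 to -0.00642. The median ran from -0.48 to 0.00589 in cDC2, -0.67 to 0.0893 in gamma-delta T cells, -0.45 to 0.0561 in macrophages, -0.50 to 0.0921 in mature dendritic cells, -0.43 to 0.0863 in monocytes, -0.44 to 0.0304 in intermediates, -0.49 to 0.133 in neutrophils and -0.62 to 0.0305 in regulatory T cells, each time highest without IgG 3. Ribosomal protein genes in gamma-delta T cells ran from -0.42 to 0.0227 (highest without IgG 3) and cell cycle genes in neutrophils from -1.31 to 0.0375 (highest without UM-h101 4).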

Other observations

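The tests of downstream genes, including that of free RNA and of handling, were chosen after the result was seen, as was the minimum of 50 CPM for the neutrophil genes read in CD8 T cells. The splits of libraries and the tests of Arg1, Arg2 and Nos2 had their outcome limits written down beforehand.

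Chance as the source of the gene counts was tested over all 35 splits of the 8 libraries into 4 and 4. Only 1 split, the real one, gave a count as large in CD8 T cells (1150, highest other 0), NK cells (658, 0), gamma-delta T cells (34, 0), macrophages (601, 0), mature dendritic cells (170, 0), monocytes (567, 0), intermediates (3768, 0), all kept cells (7280, 0), regulatory T cells (63, 1), cDC1 (20, 1), cDC2 (467, 2), CD4 T cells (47, 2) and neutrophils (203, 2). A share of 1 in 35 is the smallest this test can give, and it was not adjusted over the classes. Chance is thus made less likely for each of these counts but is not excluded. Splits that mix the groups move any group difference into the spread within groups, which by itself lowers their counts. Chance stays open for B or plasma cells (1, highest other 39, 3 splits) and erythroid cells (64, highest other 258, 2 splits), where another split gave a count as large. For pairs of a class and a list 24 of the 35 splits gave at least the real 110, the highest being 156 for IgG 1, IgG 4, UM-h101 1 and UM-h101 2, so chance is not excluded for list calls.

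Genes just downstream of abundant genes, summed, were higher in UM-h101 libraries in most classes. RNA that runs past the ends of abundant genes is a candidate explanation: the median over classes of their log2 fold change minus that of upstream genes was 0.41. Free RNA with the make-up of all kept cells is argued against. In each UM-h101 library the rise in CD8 T cells was at least 1.99 times the most that such RNA could bring. That bound was set from the kept cells and not from empty droplets, so free RNA of another make-up stays open. Handling or library preparation that differed between the groups cannot be told apart from treatment, since all 4 UM-h101 libraries lay above all IgG libraries in 11 of 14 classes and no label parts libraries within a group. IgG 3 lay apart from the other 7 in the UMIs of 4 genes linked to ribosomal RNA, 0.093% of a median kept cell against 0.702 to 1.114%. A response of the cells to the antibody also stays open and untested.

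Neutrophil genes were higher in other classes of UM-h101 libraries. Droplets holding a neutrophil and a T cell are argued against, since the 1% of CD8 T cells with the most UMIs of 6 neutrophil genes held 16.04% of them (15.1% over 12 genes). In UM-h101 libraries 355 of 2238 CD8 T cells carried at least 1 of these 424 UMIs. Free RNA from the larger neutrophil fraction cannot be told apart from other sources. It needs 1 ratio of CD8 T-cell to pooled level for all such genes, with an SD under 0.5 on the log2 scale. The SD was 0.46 over the 6 genes of at least 50 CPM but 1.799 over all 12, past the limit of 1 set against it. That limit left out counting noise, and 5 of the 6 added genes had only 4 to 7 UMIs in these CD8 T cells.

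Arg1, Arg2 and Nos2 rose in CD8 T cells. For Arg1 and Nos2 free RNA from macrophages and neutrophils may account for it, since in 0 UM-h101 libraries did their ratio to the pool lie above that of the highest macrophage gene. For Arg2 this cannot be told apart from expression by the T cells: its ratio lay above in 3 UM-h101 libraries, but also in 4 of 4 IgG libraries, where its median ratio was 11.7% against 7.88%.

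The unassigned library resembled IgG libraries in some shares without being assigned to them: macrophages 38.1% (IgG 28.03 to 46.8%, UM-h101 9.71 to 22.1%), intermediates 23.9% (14.8 to 35.2% and 37.7 to 48.9%), CD8 T cells 11.0% (5.68 to 18.1% and 4.63 to 7.11%) and regulatory T cells 1.48% (0.95 to 2.53% and 0.821 to 1.18%). Its share of NK cells, 4.47%, lay in both ranges. Its label names no treatment, so no comparison rests on it.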
